A study of Triticum aestivum with 12 samples.

How the data were processed

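RNA sequencing was done on immature wheat grain, in 3 libraries for each of 4 groups: mutant and wild type at 20 and 30 days after anthesis. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit. Adapters were trimmed with cutadapt 1.9 and reads checked with FastQC, per the submitters' processing notes; the aligner, the counting tool and the genome build are not given in the sources used here. The authors deposited a table of the whole series with, per the file headers, whole-number read counts and FPKM for each gene and library. The FPKM values deposited by the authors are counts divided by gene length and library total, and hold 1e-04 where the count is 0. Of 25270 lines the last was incomplete and was left out. Gene models in this table (12357 of them protein-coding) lie on 1A (4344), 1B (4714) and 1D (3358) alone, so statements about coding genes cover these chromosomes. The table pairs 1457 of the gene models with a functional description, 8613 with gene ontology terms and 3696 with KEGG entries. Gene names are those of the table, since 0 identifiers matched the reference table (assembly IWGSC CS RefSeq v2.1), and coordinates are those of the table, with its build not given in the sources used here.

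Because the table holds part of each library, its column sums are not the sequencing depth. Library totals were recovered from the ratio of counts to FPKM in 43 non-coding genes with at least 100 counts in each library (spread of the ratio 0.754% of its median) and came to 59.3 M to 73.6 M reads. Groups came from the labels. Genes with FPKM of 1 or more in at least 3 of the 12 libraries were tested. The test was edgeR 4.0.16's quasi-likelihood test on the deposited counts, with TMM factors on the recovered totals, group means only, all 12 libraries in a single fit, and calls at a Benjamini-Hochberg adjusted p under 0.05 (R 4.3.3). The common biological coefficient of variation was 21.2%. The planned test was limma on log2(FPKM + 1), which suits a table without counts; since the table held counts, edgeR took its place and limma became an alternative. TMM factors averaged 1.17 and 0.806 in the mutant at 20 and 30 days and 0.947 and 1.12 in wild type. A log2 fold change uses these factors, whereas a ratio of FPKM uses library totals alone. The SE given with it is its absolute value divided by the square root of the quasi-likelihood F statistic.

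Gene lists were fixed before the data were examined, as were the groups, the planned tests, most alternatives and the rule for named genes. They were 31 patterns matched to descriptions, and 19 had tested genes. Those with at least 5 tested genes, 13 in all, were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over lists within a comparison; 0 of the calls held with an estimated correlation. The patterns matched to descriptions had no tested member for phenylpropanoid, flavonoid, antioxidant, tocopherol, carotenoid, ascorbate, abscisic acid and gibberellin genes. The same held for pathogenesis-related and lipid transfer proteins, NAC and WRKY factors, and disease resistance receptors. Some genes of the enzyme pathways were reached by EC number or KEGG entry instead. The list of enzyme inhibitors matched 5 genes through the word methionine, so its thionins alone are described. The named genes of a cultivar comparison were called genes with a description, with the 3 libraries of one group above the 3 of the other (10% of genes by chance) and a mean FPKM of at least 5 in the higher group: the 6 largest rises, the 6 largest falls and the largest change in each of 12 lists. Time comparisons took the 3 largest rises and falls and the largest change in each of 8 lists, and the interaction the 5 largest of each sign. Candidates by this rule numbered 30 at 20 days, 138 at 30 days, 414 and 343 over time and 237 for the interaction; 79 called genes at 20 days and 1050 at 30 days had no description. Other list members, 515 gene ontology and KEGG terms and enzymes by EC number were chosen for mention after their values were seen. Of these terms 0 were called in any comparison with an estimated correlation.

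Group means of single values were compared with 2-sided exact permutation tests, for which 0.1 is the smallest p with 3 against 3 libraries. Alternatives were other pseudocounts, filters, scalings, spread estimates, limma, DESeq2 1.42.0, the replicate number as a block and each library left out. The steps were tested on simulated data drawn for the 5723 genes of the 30-day comparison with 200 genes changed: 68% of 100 genes changed 2-fold and 89% of 100 changed 4-fold were called, 8 unchanged genes were called, and 0 were called in an unchanged 20-day comparison. The changed genes had mean counts of at least 20, and as many rose as fell. The simulation thus does not bear on genes with lower counts or on shifts in library composition. Read counts cover counting error only through the fitted dispersion, and genes near the filter have the least precise values.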

Results

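Immature grain of bread wheat (Triticum aestivum) was profiled by RNA sequencing in 12 libraries that fell into 4 groups of 3. The groups were the mutant line HPm512 and the wild-type cultivar Zhoumai22, each collected at 20 and at 30 days after anthesis, the opening of the flower. The labels give the mutant a high antioxidant activity, and the question set by the series is which transcripts differ between grains of these cultivars at each time. Nothing in the labels says that the replicates came from separate plants, so the p-values measure the spread between these libraries, which may be technical.

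The table covered 25269 genes, of which 12416 were gene models on chromosomes 1A, 1B and 1D and 12853 were non-coding RNA genes spread over the genome. Coding genes of the other chromosomes were not analysed here. Counts over the table ranged from 9244968 to 15187939 per library, within library totals of 59.3 M to 73.6 M reads, and 8341 to 9213 genes were detected per library. Replicates of a group had log2 values that correlated across genes with r of 0.952 to 0.974 and counts that differed by more than sampling noise (chi-square per degree of freedom 10.2 to 213). In total 5723 genes had enough expression to be tested, 5071 of them gene models (5037 protein-coding and 34 non-translating). The first principal component held 66.2% of the variance and separated the times, and the second held 11.9% and separated the cultivars at each time with opposite signs, as the plot of the principal components shows. Mutant replicate 3 at 20 days stood apart from its group, at -69.2 and 4.91 on these components.

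**Figure D1:**
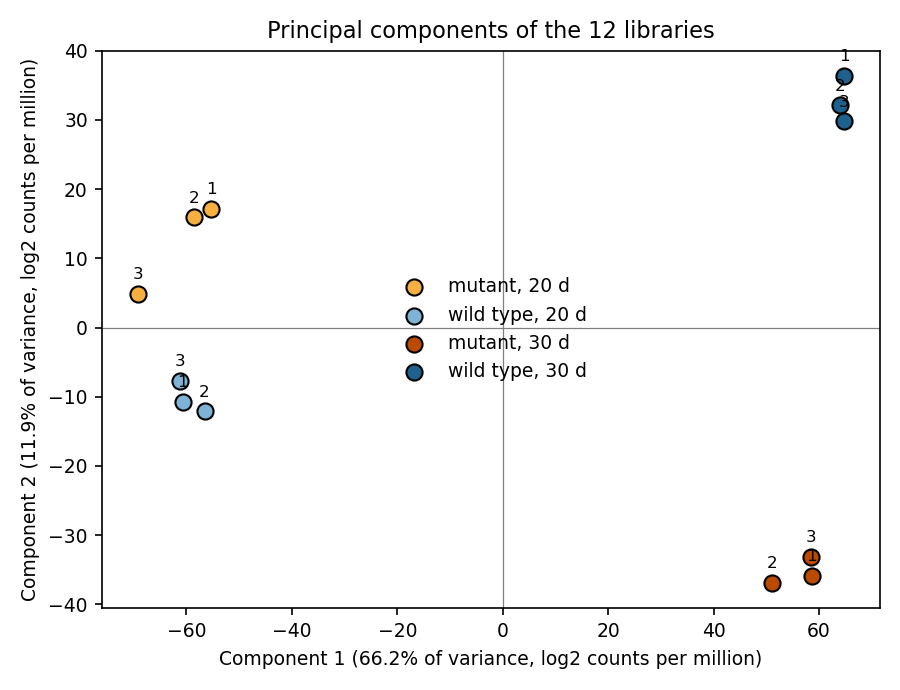
Scores of the 12 libraries on the first principal components of log2 CPM (axes: components 1 and 2, with percent of variance; colours: groups; digits: replicate numbers). On component 2 the mutant lay at 4.91 to 17.2 at 20 days and at -33.1 to -36.8 at 30 days, and wild type at -7.68 to -12.1 and at 29.8 to 36.3.

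Storage protein transcripts made up a measurable share of each library. Genes annotated with nutrient reservoir activity, which include the gliadins, took 4.95% ± 0.102 of all reads in wild type at 20 days and 0.548% ± 0.00434 at 30 days (SD, n = 3). In the mutant they took 3.15% ± 1.08 at 20 days and 3.41% ± 0.474 at 30 days. Mutant replicate 3 at 20 days held 4.31%, nearer to wild type than replicates 1 and 2, with 2.99% and 2.16%. The mutant share was 0.637 of the wild-type share at 20 days and 6.23 times it at 30 days (2-sided exact permutation p = 0.1 for each, the smallest that 3 against 3 libraries allow). The 10 most abundant genes held 40.8% ± 1.04 of the table in wild type at 20 days and 13.2% ± 0.190 at 30 days, against 30.3% ± 5.93 and 35.7% ± 2.64 in the mutant. The whole table held 22.5% ± 0.260 and 13.5% ± 0.0691 of the reads in wild type, and 18.4% ± 1.93 and 19.6% ± 0.978 in the mutant. Scaling by library totals alone put the median log2 fold change of all genes, mutant against wild type, at 0.32 at 20 days and at -0.51 at 30 days. With TMM factors these medians were 0.011 and -0.034. The fold changes given here are relative to a scaling that sets the bulk of genes near 0, so they differ from ratios of FPKM.

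At 20 days the question was which transcripts differ between the cultivars, and storage proteins were lower in the mutant. Gamma-gliadin 3 (TraesCS1B02G010400, 1B, 4965664 to 4966572), a gluten protein of the endosperm, stood at 174 ± 56.4 FPKM in the mutant and 329 ± 47.8 in wild type (SD, n = 3; log2 fold change -1.20, SE 0.26, adjusted p = 0.0369). Of 12 tested seed storage protein genes 5 fell and 0 rose, with 12 lower when adjusted over the list alone, and the list's median was -0.99 (camera adjusted p = 3.81e-14). That call was lost with adjusted p = 0.28 with an estimated correlation. The fallen members included Gamma-gliadin 2 (TraesCS1D02G001200, -1.05, adjusted p = 0.0481) and Globulin 1 (TraesCS1B02G330000, -1.13, adjusted p = 0.0252), and the direction of the list held under all scalings tried. Type V Thionin (TraesCS1B02G426000, 1B, 652297679 to 652298808), a small antimicrobial protein of the endosperm, was at 141 ± 22.7 FPKM against 238 ± 63 (-1.06, SE 0.23, adjusted p = 0.0369). The neighbouring Alpha purothionin (TraesCS1B02G426100), at 5447 ± 1071 against 7789 ± 337 FPKM, fell by 0.81 on the log2 scale (adjusted p = 0.0475). The 3 tested chlorophyll a-b binding proteins, markers of green pericarp, lay at -1.37 to -0.52, with 1 called lower. That call, of TraesCS1B02G432700 (-1.37), ended with equal FPKM totals (-0.71). With equal FPKM totals the calls of Type V Thionin (-0.41) and Alpha purothionin (-0.18) ended. With quantile normalization those of Gamma-gliadin 3 (-0.78), Gamma-gliadin 2 (0.00), Type V Thionin (-0.71) and Alpha purothionin (0.13) ended. Quantile normalization gives genes of the same rank the same value. It can thus remove differences of the most abundant genes, such as Gamma-gliadin 2 and Alpha purothionin, by construction.

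Among carbohydrate genes at 20 days, the adenylyltransferase TraesCS1A02G419600, which makes ADP-glucose for starch, was at 126 ± 21.5 FPKM in the mutant and 168 ± 8.29 in wild type (1A, 576370933 to 576375876; log2 fold change -0.70, SE 0.16, adjusted p = 0.0405), a call that ended with equal FPKM totals (-0.07). An isoamylase, a starch debranching enzyme assigned by EC number (TraesCS1A02G247100), was also lower, at 4.51 ± 0.626 against 7.99 ± 0.831 FPKM (-1.13, adjusted p = 0.00388), whereas the median of its 3 tested family members turned to 0.30 with libraries rescaled to equal FPKM totals. The pyruvate kinases of the last step of glycolysis rose on each of 1A (TraesCS1A02G213000, 0.56), 1B (TraesCS1B02G226500, 0.69) and 1D (TraesCS1D02G215900, 0.76). The 1D copy was at 6.05 ± 1.79 against 2.85 ± 0.268 FPKM. A sugar transporter of the SWEET family (TraesCS1B02G276000) was at 1.76 ± 1.00 against 0.394 ± 0.193 FPKM (1.80, adjusted p = 0.0369).

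Single genes that rose at 20 days included a DNA helicase and a structural maintenance of chromosomes protein. The DNA helicase, which unwinds DNA (TraesCS1A02G299500, 1A, 494442747 to 494448514), was at 10.6 ± 2.45 FPKM in the mutant and 5.03 ± 1.05 in wild type (log2 fold change 0.76, SE 0.17, adjusted p = 0.0369). The structural maintenance protein (TraesCS1A02G428700) was at 19.7 ± 2.65 against 9.76 ± 1.44 (0.71, SE 0.12, adjusted p = 0.0161), and a regulatory subunit of a serine/threonine phosphatase (TraesCS1B02G408600) rose by 0.60. The cell division list, 85 histones and 9 kinesin-like proteins, had a median of 0.58 and a call upward as a list (camera adjusted p = 6.19e-11; adjusted p = 0.28 with an estimated correlation). With edgeR 0 of these 94 genes passed, with 23 higher at an unadjusted p under 0.05, and DESeq2 called 5 and limma 75 higher. Cytosolic ribosomal proteins had a median of 0.26 over 16 genes (camera adjusted p = 1.08e-05; adjusted p = 0.28 with an estimated correlation). For them edgeR called 0, or 3 higher adjusted over the list alone, with 11 at an unadjusted p under 0.05, against 8 higher with DESeq2 and 16 with limma. A pair of the 3 tested flavonol synthases, enzymes of flavonoid synthesis assigned by EC number, were higher (TraesCS1A02G221200, 1.58, adjusted p = 0.0418; TraesCS1A02G320000, 15.4 ± 4.49 against 6.23 ± 2.16 FPKM, 0.98, adjusted p = 0.0481).

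Among the genes named by the planned rule, non-coding transcripts gave the largest falls at 20 days. The RNA of the signal recognition particle (SRP), which guides secreted proteins to the endoplasmic reticulum, was at 19.3 ± 1.71 RPM in the mutant and 56.4 ± 25.7 in wild type (2-sided exact permutation p = 0.1, the smallest possible). Of its genes ENSRNA050021664 fell by 1.83 on the log2 scale (SE 0.22, 2.47 ± 0.522 against 7.17 ± 1.76 FPKM, adjusted p = 0.00376). ENSRNA050017176, ENSRNA050021164, ENSRNA050021163 and ENSRNA050021162 gave -2.71, -2.10, -1.79 and -1.73. A small subunit rRNA gene, ENSRNA050019260, gave -1.90. Ribosomal RNA stood at 431 ± 22.8 RPM in the mutant and 810 ± 326 in wild type (exact permutation p = 0.2), with 1023 and 972 in wild-type replicates 2 and 3. SRP RNA moved with rRNA in wild type: it was 74.4 and 67.8 RPM in these replicates. In wild-type replicate 1, where rRNA was 434, SRP RNA was 27.0, against 17.6 to 21.0 in the mutant libraries. The 20-day difference in SRP RNA thus lay mostly in the rRNA-rich libraries. Copies of SRP RNA, rRNA, histone and gliadin genes share sequence, so values of single copies are uncertain.

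By edgeR's quasi-likelihood test, the number of genes differing between mutant and wild type at 20 days was 131 of 5723 (24 higher, 107 lower; 1230 at an unadjusted p under 0.05), of which 60 changed at least 2-fold (3 higher, 57 lower). This count rested on single libraries: it was 11, 13 and 414 without mutant replicate 1, 2 or 3, and 45, 12 and 58 without wild-type replicate 1, 2 or 3, and leaving out 30-day libraries, which share the fit, gave 79 (mutant 3), 61 (wild type 1) and 39 (wild type 2). Of the 15 genes named by rule at this time, 14 lost their call without at least 1 library, and ENSRNA050021664 kept it throughout. A fit of the 6 libraries alone called 2 genes, and without the 3 libraries richest in rRNA, which leaves 1 wild-type library, edgeR called 0 (765 at an unadjusted p under 0.05), DESeq2 117 and limma 66. The split also moved with the scaling: library totals alone gave 1392 higher and 123 lower, equal FPKM totals 3368 and 67, quantile normalization 142 and 130, median-of-ratios factors 43 and 102, and DESeq2 216 and 307. Limma on log2(FPKM + 1), the planned test, called many more genes than edgeR, a count given below with the other settings.

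**Figure D2:**
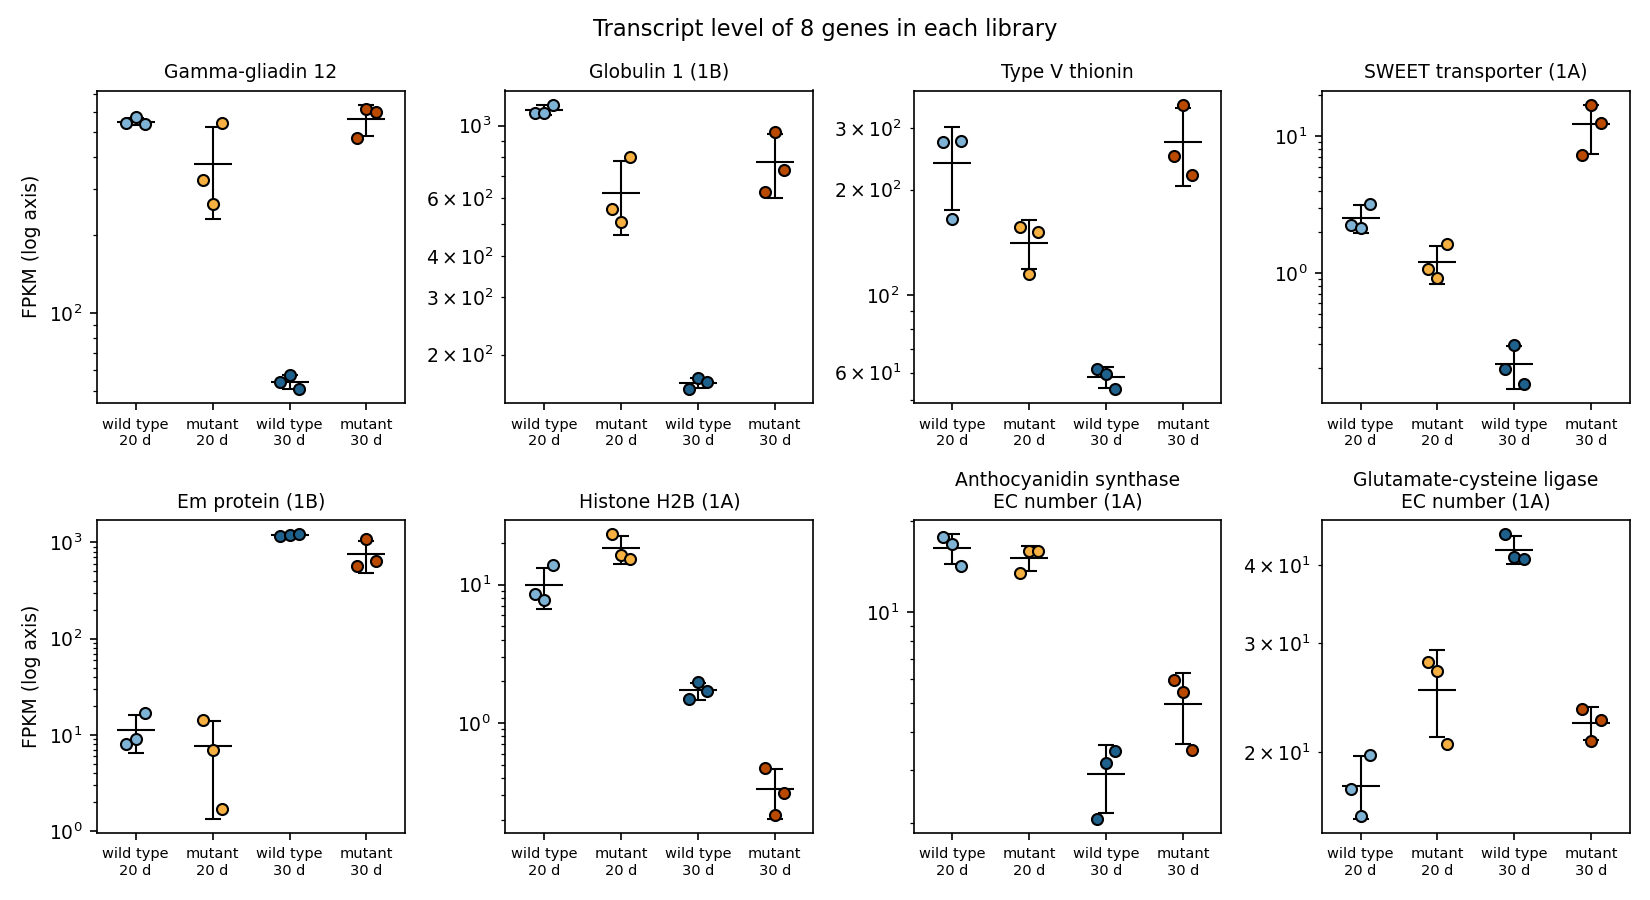
FPKM of 8 genes in each library on a log axis, by group, with points for libraries and bars for the mean ± SD (n = 3). Gamma-gliadin 12 fell from 549 ± 18.02 to 54.2 ± 3.39 FPKM over time in wild type, whereas its mutant means were 377 ± 146 and 561 ± 76.5.

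At 30 days the same question gave the reverse order for storage proteins: all 12 tested genes rose in the mutant relative to wild type. Gamma-gliadin 12 (TraesCS1D02G001000, 1D, 250463 to 251359) was at 561 ± 76.5 FPKM in the mutant and 54.2 ± 3.39 in wild type (SD, n = 3; log2 fold change 3.85, SE 0.27, adjusted p = 7.19e-07). The most abundant member, Gamma-gliadin 2 (TraesCS1D02G001200), was at 11316 ± 1435 against 1563 ± 24.7 FPKM (3.33), and Globulin 1 (TraesCS1B02G330000) at 773 ± 170 against 164 ± 6.13 (2.71). The largest rise in the list was Gamma-gliadin B (TraesCS1B02G011000, 4.44, SE 0.43, adjusted p = 5.76e-06), at 5.58 ± 1.65 against 0.351 ± 0.136 FPKM. The list's median was 3.06 and its direction held under all scalings tried (camera adjusted p = 8.78e-28; adjusted p = 0.0786 with an estimated correlation). Type V Thionin (TraesCS1B02G426000) was at 273 ± 67.8 against 58.3 ± 3.94 FPKM (2.70, SE 0.24, adjusted p = 3.59e-06), and Alpha purothionin (TraesCS1B02G426100) at 4778 ± 397 against 1250 ± 14.4 (2.41, adjusted p = 1.91e-06). With quantile normalization Alpha purothionin was at 0.15 and not called, where a gene this abundant can lose its difference by construction.

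Among the genes named by the planned rule, the largest rise at 30 days was that of a bidirectional sugar transporter of the SWEET family (TraesCS1A02G050400, 1A, 32260043 to 32262299). It stood at 12.2 ± 4.79 FPKM in the mutant and 0.216 ± 0.0742 in wild type (log2 fold change 6.24, SE 0.42, adjusted p = 5.48e-07). Of 6 tested SWEET genes TraesCS1D02G052700 also rose (5.09; 2.19 ± 0.91 against 0.0863 ± 0.106 FPKM) and TraesCS1A02G265200 fell (-1.13; 2.92 ± 0.148 against 8.92 ± 0.0516). As a list they were not called (camera adjusted p = 0.318). The adenylyltransferase of starch synthesis TraesCS1A02G419600 was at 82 ± 8.13 against 64.4 ± 2.75 FPKM (0.82, SE 0.16, adjusted p = 0.0022), a call that ended with equal FPKM totals, where the value turned to -0.29. Of 8 starch synthases by EC number 3 rose (TraesCS1B02G119300, 3.34; TraesCS1A02G091500, 2.07; TraesCS1D02G100100, 1.34) and 1 fell (TraesCS1A02G353300, -1.30, adjusted p = 0.000305), with 2 higher and 5 lower with equal FPKM totals, where TraesCS1D02G100100 was not called (0.23). The KEGG set of starch and sucrose metabolism had 21 of 63 genes higher and 5 lower (camera adjusted p = 0.0123; adjusted p = 0.775 with an estimated correlation), with a median of 0.28 that turned to -0.83 with equal FPKM totals, -0.19 with library totals alone and -0.15 with limma. The wheat lectin Agglutinin isolectin 1 (TraesCS1A02G326800, 1A, 516739314 to 516740335), which binds chitin, was at 53.3 ± 7.93 against 210 ± 2.22 FPKM (-1.51, SE 0.35, adjusted p = 0.00702). Among 3 tested chlorophyll a-b binding proteins, markers of green pericarp, 2 were higher, and all 3 lay at 1.37 to 3.59. The call of TraesCS1B02G432700 (1.37) ended with equal FPKM totals (0.29), library totals alone (0.91), limma (0.07) and quantile normalization (0.15).

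Most cytosolic ribosomal protein genes and some cell division genes were lower in the mutant at 30 days. Of 16 cytosolic ribosomal protein genes 14 fell and 0 rose, or 16 when adjusted over the list alone, with a median of -0.49 (camera adjusted p = 2.73e-06; adjusted p = 0.419 with an estimated correlation). The 40S protein S4 (TraesCS1A02G092900) was at 327 ± 24.3 FPKM in the mutant and 653 ± 14.8 in wild type (-0.53, adjusted p = 0.00267). The cell division list had 15 falls and 0 rises among 94 genes, or 14 falls adjusted over the list alone, with a median of -0.75 (camera adjusted p = 4.09e-06; adjusted p = 0.592 with an estimated correlation and 0.733 with camera on log2(FPKM + 1)). Both directions held under all scalings tried. Ribosome genes by KEGG pathway had 51 falls and 3 rises among 106 genes (camera adjusted p = 4.24e-09; adjusted p = 0.775 with an estimated correlation).

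Among genes tied to antioxidant chemistry, a class III peroxidase (TraesCS1A02G124200, 1A, 146630196 to 146634893), an enzyme that oxidises phenolics with hydrogen peroxide, was at 2.46 ± 0.183 FPKM in the mutant and 6.67 ± 0.242 in wild type at 30 days (log2 fold change -0.96, SE 0.13, adjusted p = 0.000111). Another (TraesCS1A02G077700) rose by 0.86, a call that ended with equal FPKM totals (-0.24), library totals alone (0.39), limma (0.17) and quantile normalization (0.35), and as a list the 7 tested peroxidases were not called (camera adjusted p = 0.446). The 3 tested anthocyanidin synthases, enzymes of flavonoid synthesis assigned by EC number, rose with TMM factors. With equal FPKM totals, which shift all genes downward at this time, edgeR called 0 of them, and 0 at an unadjusted p under 0.05. DESeq2 called 3, limma 1 and library totals alone 2. They were TraesCS1A02G070200 (1.24, SE 0.21, adjusted p = 0.000728; 4.96 ± 1.30 against 2.90 ± 0.732 FPKM), TraesCS1B02G088600 (1.32) and TraesCS1D02G072700 (0.82, turned to -0.29 with equal FPKM totals). The flavonol synthase TraesCS1A02G320000, higher in the mutant at 20 days, was lower at 30 days (-1.11), a call that ended with quantile normalization (-0.60). The 3 copies of glutamate-cysteine ligase, which makes the first step of glutathione synthesis, fell by a median of 0.37 on the log2 scale with TMM factors. The direction held under all scalings. TraesCS1A02G072000 was at 22.3 ± 1.36 against 42.3 ± 2.15 FPKM (-0.45, adjusted p = 0.00743). A pair of thioredoxins, small proteins that reduce disulfides, rose (TraesCS1B02G339000, 1.79, adjusted p = 0.00558; TraesCS1B02G132600, 0.79, adjusted p = 0.00824) among 7 tested, or 3 adjusted over the list alone, without a call for the list (camera adjusted p = 0.216). With equal FPKM totals neither was called (0.68 and -0.33), nor was TraesCS1B02G132600 with library totals alone (0.31) or limma (0.24). The wider KEGG sets of phenylpropanoid (9 of 28 genes higher, 2 lower), flavonoid (6 of 15 higher, 2 lower) and glutathione metabolism (4 of 37 higher, 9 lower) were not called at 30 days (camera adjusted p = 0.697, 0.917 and 0.24). By EC number and with TMM factors, 1 of 3 tocopherol cyclases was lower and 0 higher at 30 days. Of 2 GDP-mannose 3,5-epimerases, enzymes of ascorbate synthesis, 1 was higher and 0 lower. Among 5 homogentisate solanesyltransferases and 9 genes of the KEGG carotenoid set 0 were called. At 20 days 0 genes of these 4 groups were called.

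Non-coding RNA differed in both directions at 30 days. SRP RNA was at 253 ± 59.9 RPM in the mutant and 60.2 ± 31.2 in wild type, 4.21 times as much (2-sided exact permutation p = 0.1, the smallest possible), and ENSRNA050015611, ENSRNA050015609 and ENSRNA050015610 rose by 5.10, 4.53 and 4.06 on the log2 scale. Within each group SRP RNA moved with rRNA. Mutant replicates 1 to 3 held 319, 238 and 202 RPM, with rRNA at 533, 420 and 377. In wild type it was 37.3, 47.5 and 95.7 RPM, with rRNA at 449, 533 and 1257. How far levels of non-coding RNA depend on library preparation was not tested. Falls were those of rRNA genes ENSRNA050016272 (-3.07), ENSRNA050016023 (-2.07), ENSRNA050014871 (-2.02) and ENSRNA050020567 (-1.85) and of the small nucleolar RNA U54 (ENSRNA050019618, -2.28). ENSRNA050020567 lost its call without wild-type replicate 3 (-1.37), which held the most rRNA of all libraries, 1257 RPM; the groups held 443 ± 80.5 and 747 ± 445 (exact permutation p = 0.2).

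By edgeR the number of genes differing between mutant and wild type at 30 days was 1312 of 5723 (780 higher, 532 lower; 2012 at an unadjusted p under 0.05), of which 532 changed at least 2-fold (421 higher, 111 lower). The split turned with the scaling: it was 412 higher and 2595 lower with library totals alone, 391 and 2637 with limma on log2(FPKM + 1), 238 and 4321 with equal FPKM totals, 664 and 825 with upper-quartile factors, and 626 and 735 with quantile normalization.

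**Figure D3:**
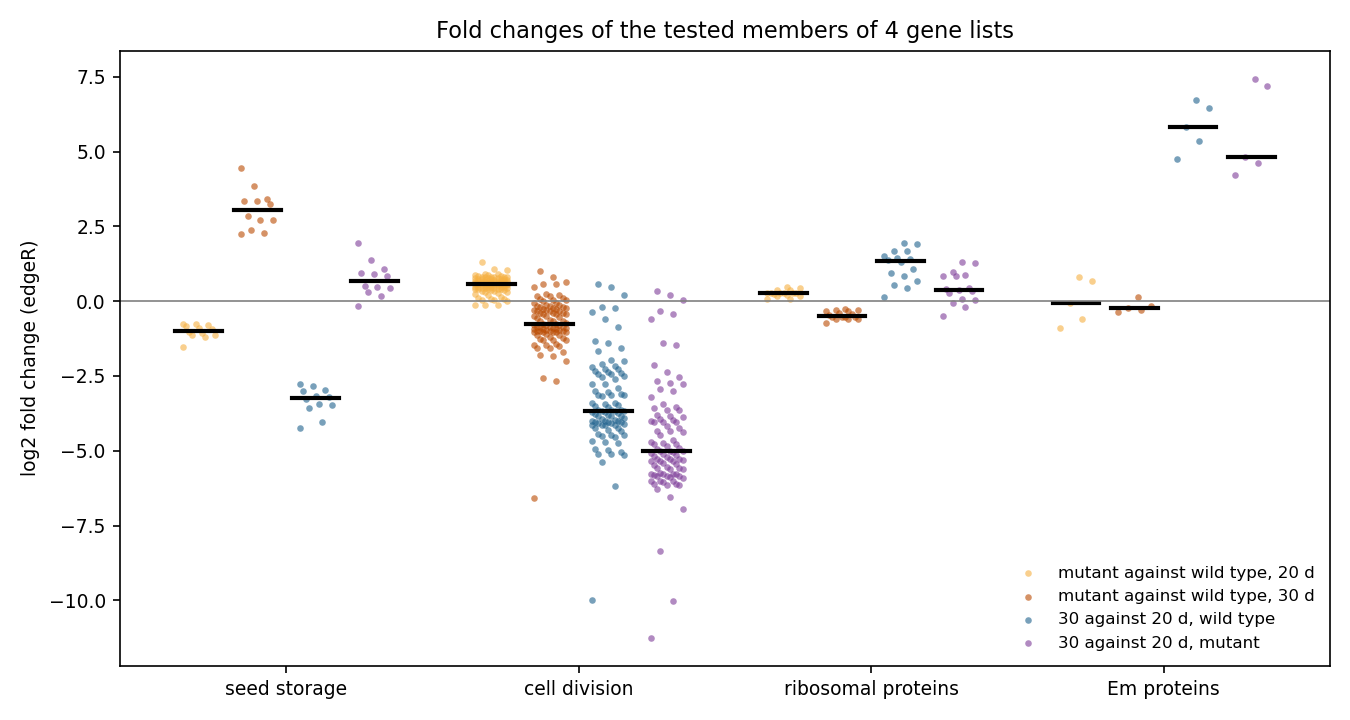
log2 fold changes from edgeR of the tested members of 4 gene lists in 4 comparisons (points: genes; black lines: medians), where members at 0 counts in a group, 2 at 30 days, 1 in wild type over time and 2 in the mutant over time, have values that depend on the prior count. Storage proteins had medians of -0.99 at 20 days and 3.06 at 30 days, and directions turn with the scaling for ribosomal and storage proteins in the mutant over time and for Em proteins between cultivars at 20 days.

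From 20 to 30 days in wild type, the comparison that follows grain development in the reference cultivar, proteins of late embryo development rose and storage proteins and histones fell. The Em proteins, hydrophilic proteins that accumulate as the embryo desiccates, rose in 5 of 5 tested genes with a median of 5.83 (camera adjusted p = 0.0497; adjusted p = 0.563 with an estimated correlation). The 1B copy (TraesCS1B02G237500, 1B, 424531353 to 424532121) went from 11.3 ± 4.84 to 1177 ± 25.7 FPKM (SD, n = 3; log2 fold change 6.46, SE 0.61, adjusted p = 8.48e-07). The 1D copy (TraesCS1D02G226000) went from 2.65 ± 3.01 to 333 ± 19.5 FPKM (6.71, SE 0.78), and the 1A copy (TraesCS1A02G224100) rose by 5.83. All 12 storage protein genes fell, with a median of -3.24 (camera adjusted p = 8.77e-09; adjusted p = 0.398 with an estimated correlation), and Gamma-gliadin 3 (TraesCS1B02G010400) went from 329 ± 47.8 to 20.6 ± 1.51 FPKM (-4.24, SE 0.29). The starch adenylyltransferase TraesCS1B02G449700 went from 193 ± 76.5 to 37.3 ± 8.89 FPKM (-2.62, SE 0.29), and both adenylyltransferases by EC number fell, with a median of -2.12.

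Of 94 cell division genes 88 fell and 2 rose in wild type over time, with a median of -3.66 (camera adjusted p = 2.15e-16; adjusted p = 0.398 with an estimated correlation), and a histone H2A (TraesCS1A02G132400) gave -6.18 (SE 0.55). Cytosolic ribosomal proteins went the other way, with 15 of 16 higher and a median of 1.34 (camera adjusted p = 9.31e-09; adjusted p = 0.398 with an estimated correlation), and 60S protein L18a (TraesCS1B02G427900) went from 66.2 ± 6.69 to 292 ± 9.88 FPKM. The directions of these lists held under all scalings. A defensin, an antimicrobial peptide (TraesCS1A02G014000), went from 25 ± 2.98 to 0.133 ± 0.23 FPKM (-7.65, SE 0.65), and a tryptophan aminotransferase-related protein (TraesCS1D02G114800) gave -5.86 (SE 0.44). Heat shock transcription factor A6e (TraesCS1A02G375600) went from 12.7 ± 1.17 to 5.69 ± 0.87 FPKM (-1.39, SE 0.15), and a cysteine proteinase inhibitor (TraesCS1B02G322100) gave -1.05. Both calls ended with equal FPKM totals (-0.33 and 0.00). All 3 chlorophyll a-b binding proteins fell, with values of -6.02 to -5.06. The SWEET gene TraesCS1A02G050400 gave -3.73, whereas TraesCS1D02G265400 went from 0.487 ± 0.171 to 10.1 ± 0.676 FPKM (4.10). Of 20 glutathione S-transferases by EC number 11 rose and 4 fell, with a median of 1.41, a direction that held under all scalings. All 3 glutamate-cysteine ligases rose (median 1.02), and the 3 anthocyanidin synthases and 3 flavonol synthases fell (medians -2.72 and -1.86). The call of the flavonol synthase TraesCS1A02G221200 (-1.46) ended with equal FPKM totals (-0.41), limma (-0.33) and quantile normalization (-0.19).

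By edgeR the number of genes differing between 30 and 20 days in wild type was 3645 of 5723 (1819 higher, 1826 lower; 3834 at an unadjusted p under 0.05), of which 2196 changed at least 2-fold (1006 higher, 1190 lower). Library totals alone, which put the median of all genes at 0.23, gave 2269 higher and 1469 lower. Limma on log2(FPKM + 1) gave 2346 and 1477, and equal FPKM totals gave 3563 and 767.

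In the mutant the same comparison over time showed Em proteins rising and histones falling. All 5 Em genes rose, with a median of 4.82 (camera adjusted p = 0.0454; adjusted p = 0.553 with an estimated correlation), and the 1B copy (TraesCS1B02G237500) went from 7.6 ± 6.24 to 757 ± 279 FPKM (SD, n = 3; log2 fold change 7.20) and the 1D copy (TraesCS1D02G226000) from 2.11 ± 2.65 to 260 ± 122 (7.43). Of 94 cell division genes 90 fell and 1 rose, with a median of -5.02 (camera adjusted p = 2.02e-39; adjusted p = 0.191 with an estimated correlation). Histone H4 variant TH011 (TraesCS1D02G081600, 1D, 63681763 to 63682074) went from 16.8 ± 5.91 FPKM to 0 counts in all 3 libraries, at least 245-fold lower against a floor of 3 counts over the group. A histone H3 (TraesCS1A02G361900) gave -8.35, and another H4 variant TH011 (TraesCS1B02G376600) went from 14.1 ± 1.51 to 0.0655 ± 0.057 FPKM (-6.94).

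Of 12 storage protein genes 7 rose and 0 fell in the mutant over time, with a median of 0.68 that turned to -0.01 with equal FPKM totals and -0.17 with quantile normalization, and the list was not called (camera adjusted p = 0.189). Nutrient reservoir genes by gene ontology had 6 higher and 1 lower among 18 (TraesCS1D02G046400, -0.51), also not called (camera adjusted p = 0.505). Gamma-gliadin B (TraesCS1B02G011000) rose by 1.94 (SE 0.37) and Gamma-gliadin 11 (TraesCS1D02G001100) by 1.36. Ribosomal proteins had 10 rises and 1 fall among 16 (11 and 1 adjusted over the list alone), with a median of 0.38 that turned to -0.33 with equal FPKM totals, -0.15 with library totals alone and with limma, and -0.03 with quantile normalization. That list was called (camera adjusted p = 0.0454), but had adjusted p = 0.707 with an estimated correlation and 0.264 with camera on log2(FPKM + 1). Serine-type endopeptidase inhibitors by gene ontology rose in 20 of 26 genes and fell in 1, with a median of 1.18 that kept its sign under all scalings (camera adjusted p = 0.00095; adjusted p = 0.363 with an estimated correlation). The SWEET gene TraesCS1A02G050400 rose by 3.87. Of the 3 chlorophyll a-b binding proteins 2 fell, with all 3 at -3.27 to -0.85. The starch adenylyltransferase TraesCS1B02G449700 gave -0.88 (adjusted p = 0.0146), a call lost without 20-day mutant replicate 3 (-0.64), and the cysteine proteinase inhibitor TraesCS1B02G322100 gave -0.51 (adjusted p = 0.0352), lost without 20-day mutant replicate 2 (-0.27) or 30-day mutant replicate 1 (-0.55) or 3 (-0.40). The 3 flavonol synthases fell (median -3.83), as did the 3 anthocyanidin synthases (-1.07). SRP RNA was 13.1 times as abundant at 30 days (2-sided exact permutation p = 0.1, the smallest possible), against 1.07 times in wild type (exact permutation p = 0.9), and ENSRNA050015611 rose by 7.36 on the log2 scale. rRNA ratios over time were 1.03 in the mutant and 0.922 in wild type (exact permutation p = 0.9 and 1).

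By edgeR the number of genes differing between 30 and 20 days in mutant grain was 3308 of 5723 (1711 higher, 1597 lower; 3520 at an unadjusted p under 0.05), of which 1712 changed at least 2-fold (832 higher, 880 lower). Library totals alone put the median of all genes at -0.46. For genes differing between 30 and 20 days in mutant, they gave 772 higher and 2708 lower. Limma on log2(FPKM + 1) gave 826 and 2776, and equal FPKM totals gave 515 and 2955.

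The design also asks whether the cultivar difference itself changed between the times, tested as an interaction. The difference moved upward in all 12 storage protein genes, with a median of 4.09 (camera adjusted p = 7.09e-30; adjusted p = 0.0564 with an estimated correlation), and Gamma-gliadin B (TraesCS1B02G011000) gave 5.98 (SE 0.56, n = 3 per group). The SWEET gene TraesCS1A02G050400 gave 7.60 (SE 0.54), and the SRP RNA genes ENSRNA050015611, ENSRNA050015609 and ENSRNA050015610 gave 7.97, 5.98 and 5.58. The difference moved downward in 28 of 94 cell division genes and upward in 0, or downward in 33 adjusted over the list alone (median -1.32, camera adjusted p = 2.92e-09; adjusted p = 0.417 with an estimated correlation). It moved downward in 15 of 16 ribosomal protein genes, or 16 adjusted over the list alone (median -0.68, camera adjusted p = 1.3e-07; adjusted p = 0.318 with an estimated correlation). All these list directions held under all scalings. Single histones were H3.2 (TraesCS1D02G274300, -2.62, SE 0.59), H2B (TraesCS1A02G229100, -2.38, SE 0.41) and H4 (TraesCS1A02G291500, interaction value -2.47, SE 0.69). The H4 call was lost without 20-day mutant replicate 1 (-2.29, adjusted p = 0.0503) and without 30-day wild-type replicate 2 (-2.23, adjusted p = 0.0534). The fitted value of H4 variant TH011 (TraesCS1D02G081600), -7.10, depends on the prior count because a group was at 0. The SWEET gene TraesCS1B02G276000 gave -2.58 (SE 0.53). The difference moved upward in 2 of 3 chlorophyll a-b binding proteins, with all 3 at 2.44 to 4.81. The call of TraesCS1B02G432700 (2.75) ended with equal FPKM totals (1.00).

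By edgeR the number of genes whose cultivar difference changed between 20 and 30 days was 1374 (751 upward, 623 downward; 2085 at an unadjusted p under 0.05), of which 735 changed by at least 2-fold (499 upward, 236 downward). Library totals alone, which put the median at -0.80, gave 361 upward and 2994 downward. Limma on log2(FPKM + 1) gave 347 and 3141, equal FPKM totals 196 and 4468, and quantile normalization 620 and 901.

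Genes called between cultivars at both times mostly had opposite signs. Of the 107 genes lower in the mutant at 20 days 82 were higher at 30 days, against 14.6 by chance (2-sided Fisher's exact p = 1.46e-50), and of the 24 higher at 20 days 11 were lower at 30 days, against 2.23 (Fisher's exact p = 3.28e-06). These counts follow the calls at 20 days: with a library left out the 82 ranged from 9 without 20-day mutant replicate 1 (of 11 lower, against 1.47 by chance) to 200 without replicate 3 (of 260, against 37.8). The 11 ranged from 0 to 78, and the 93 genes below were 17 under the replicate block. In the same direction 3 genes were lower at both times, against 9.95 by chance (Fisher's exact p = 0.017), and 0 were higher at both, against 3.27 (Fisher's exact p = 0.0656). Fisher's test takes genes as independent, which copies of gliadin, histone and SRP RNA genes need not be. Both sets of calls also share a fit, so these p-values do not measure the spread between libraries. The number of genes called in opposite directions at 20 and 30 days was 93 with edgeR, 268 with DESeq2 and 1223 with limma, against 3, 11 and 17 in the same direction. As a measure without a test, 75 genes differed at least 2-fold with all 6 libraries of the crossed grouping (mutant at 20 days with wild type at 30 days) apart from the other 6, against 4 genes for the grouping by cultivar. Across 5723 genes, which are not independent replicates, the log2 differences at both times had Pearson's r of -0.20 and Spearman's rho of -0.34.

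None of the other lists was called as a list in any comparison, and genes called are given in the order 20 days, 30 days, wild type over time, mutant over time and interaction. Peroxidases had 0, 1, 3, 2 and 1 genes higher and 0, 1, 3, 3 and 1 lower. Thioredoxins had 0, 2, 1, 1 and 2 higher and 0, 0, 3, 0 and 0 lower. For both lists edgeR called 0 at 20 days, as it did at an unadjusted p under 0.05 and as DESeq2 did, and limma called 0 peroxidases and 2 thioredoxins. Starch synthesis enzymes had 0, 1, 5, 2 and 2 higher and 1, 1, 2, 2 and 2 lower among 7. SWEET genes had 1, 2, 3, 3 and 2 higher and 0, 1, 2, 0 and 3 lower among 6. Proteasome subunits had 8 of 9 lower in wild type and 5 of 9 lower in the mutant over time, a direction that turned to a median of 0.67 in wild type with equal FPKM totals. Em proteins between cultivars had medians of -0.08 at 20 days and -0.22 at 30 days, with 0 calls by edgeR at either time, 0 at an unadjusted p under 0.05, 0 by DESeq2 and, by limma, 0 at 20 days and 1 lower at 30 days; the 20-day sign turns with the scaling.

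Over time, the 6 tested MYB transcription factors had 3 genes higher and 3 lower in each cultivar. The 5 genes of the respiratory chain had 2 higher and 1 lower in wild type and 0 higher and 3 lower in the mutant. The list of cell death and storage proteolysis held cysteine proteinase inhibitors and a flap endonuclease, not proteases, and had 3 higher and 2 lower in wild type and 2 and 2 in the mutant. With equal FPKM totals the respiratory chain had 5 higher in wild type and 5 lower in the mutant, and the list of cell death 6 higher and 5 lower. At 30 days 2 of 3 beta-amylases matched by description were higher in the mutant, a direction that turned to a median of -0.21 with equal FPKM totals. By EC number 4 of 6 were higher, with a median of 0.74 that turned to -0.36 with equal FPKM totals. All 3 protein disulfide isomerases, which fold secreted proteins, rose in wild type over time by 0.27 to 0.37 on the log2 scale, of which quantile normalization called 1, and had 0 higher and 1 lower in the mutant (-0.26 to -0.07). All 3 cellulose synthases fell, at -0.89 to -0.35 in wild type and -0.90 to -0.27 in the mutant, with a wild-type median that turned to 0.18 with equal FPKM totals. In wild type TraesCS1A02G116200 (-0.35) was not called with library totals alone (-0.11) or limma (-0.09), and rose by 0.71 with equal FPKM totals.

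**Figure D4:**
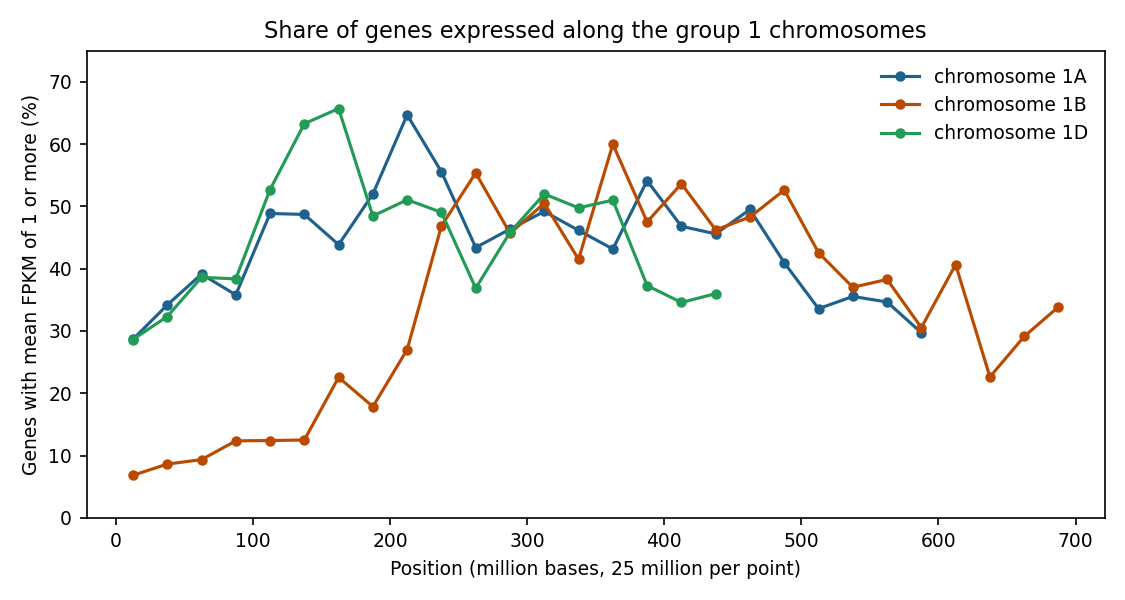
Percent of genes with a mean FPKM of 1 or more in bins of 25 Mb along 1A, 1B and 1D (x axis: position in Mb; lines: chromosomes). In the first 225 Mb 11.3% of genes on 1B passed this level, against 37.0% on 1A and 39.5% on 1D.

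Along the chromosomes, expression was sparse in the first part of 1B. There 168 of 1481 genes had a mean FPKM of 1 or more over the 12 libraries, 11.3%, whereas the rest of 1B had 39.8%, as the plot of expressed genes by position shows. Gamma-gliadin 3 and Gamma-gliadin B lie in that part, at 329 ± 47.8 and 4.99 ± 0.647 FPKM in wild type at 20 days, against 549 ± 18.02 for Gamma-gliadin 12 on 1D. Gliadin copies share sequence, so reads assigned to these 1B genes may come from copies elsewhere, which was not tested.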

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

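The tests of library scaling, exchanged labels, slower development and shared reads in this part were chosen after the results were seen; the counts of other splits of the libraries were planned. The exchange test took the place of an earlier count, 71 genes separated in the same direction at both times against 28.6 by chance, because an exchange turns same into opposite and that count could not bear on it. The bound on cell division genes was added to the test of slower development when its values were known.

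The cultivar difference changed between 20 and 30 days in 1374 genes by the interaction test, and each result in this paragraph stood out because that test found the difference to change. Seed storage proteins had a median interaction of 4.09, cell division genes -1.32 and cytosolic ribosomal proteins -0.68. Single genes were the SRP RNA genes ENSRNA050015611 (7.97), ENSRNA050015609 (5.98) and ENSRNA050015610 (5.58), the SWEET gene TraesCS1A02G050400 (7.60) and Gamma-gliadin B (TraesCS1B02G011000, 5.98). Downward values were those of H4 variant TH011 (TraesCS1D02G081600, -7.10, dependent on the prior count), H3.2 (TraesCS1D02G274300, -2.62), the SWEET gene TraesCS1B02G276000 (-2.58), H4 (TraesCS1A02G291500, -2.47) and H2B (TraesCS1A02G229100, -2.38). Of 100 regroupings of the libraries within each time, drawn from 200, 1 (the real one) gave as many genes, and the highest other gave 844. Regroupings that mix the cultivars at 30 days add their difference to the spread. This keeps their counts low whether or not the difference changed with time, so these counts cannot exclude chance for the interaction. Exchanging the cultivar labels at one time, which was among those drawn, gave 430.

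For the comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. In each of them 1 split, the real one, gave its own count: 131 genes at 20 days, 1312 at 30 days, 3645 in wild type over time and 3308 in the mutant over time. The highest other split gave 1, 1, 41 and 1 genes.

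The first pattern is that the cultivars differed in opposite directions at the 2 times. The scaling of the libraries is argued against: with each library centred on its own median, genes separated at both times in opposite directions were 6.17 times those in the same direction (617 and 100, against 28.6 by chance; 10% of genes separate by chance at a time), and 8.52 times with TMM factors. A slower course of development in the mutant at both times would put the correlation with the wild-type time course below 0 at 20 days. It was 0.127 (0.0552 to 0.207). That argues only weakly against such a course, since genes are not independent and the estimates share libraries. Cell division genes, which fall with time in wild type, had a 20-day median of 0.58, on the side of a slower course. Storage proteins, which also fall with time in wild type (20-day median -0.99), and ribosomal proteins, which rise (0.26), lay on the other side. At 30 days the correlation was -0.339 (-0.345 to -0.330), so a slower course at 30 days alone is not covered by this test. Cell division genes at 30 days had a median of -0.75, but as a list camera adjusted p = 0.592 with an estimated correlation and 0.733 with camera on log2(FPKM + 1). Cultivar labels exchanged at one of the times may account for it: 75 genes differed at least 2-fold with all 6 libraries of the crossed grouping apart, against 4 for the labelled grouping (134 and 11 at any size, 12.4 by chance). A cultivar difference that turns with time would give the same counts, so it stays open beside an exchange.

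The second pattern is that storage protein transcripts were lower in wild type than in the mutant at 30 days. Scaling is argued against, since the list's median ranged from 1.87 to 3.06 over all scalings. Reads shared among the genes of the list are argued against. The lowest mutant library had 4.94 times the highest wild-type share of reads over the whole list, and the group means differed 5.90 times. Reads shared with copies outside the list, such as those on chromosomes that were not analysed, were not tested and stay open. A difference between the cultivars could be the cause, as a hypothesis, but it and exchanged labels at 30 days (75 genes in the crossed grouping) remain open. A slower course in the mutant at 30 days alone was not tested and stays open too.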

How the results depend on the processing

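Limma and camera on log2(FPKM + 1) were the planned tests and became alternatives after the table was seen to hold counts. DESeq2, library totals alone, gene models alone, libraries left out for the overlap, leaving out rRNA-rich libraries or 20-day mutant replicate 3 for the lists, and all scalings of named genes but median-of-ratios factors were chosen after the data were seen; the other settings were planned. For genes differing between mutant and wild type at 20 days (131), pseudocounts of 0.1, 0.5 and 1 in limma gave 1415, 1594 and 1685, equal FPKM totals 3435, quantile normalization 272, array weights 508, DESeq2 523, library totals alone 1515, only the 6 libraries 2, and a 2-fold minimum 60. For genes differing between mutant and wild type at 30 days (1312) the same pseudocounts gave 3026, 3051 and 3028, equal totals 4559, library totals alone 3007 and the 2-fold minimum 532. For genes whose cultivar difference changed between 20 and 30 days (1374) they gave 3375, 3458, 3488, 4664, 3355 and 735. Limma on FPKM, equal totals and library totals alone leave the median gene off 0, which moves the counts by construction; the cause of the other shifts was not tested, except that a fold minimum or a filter at FPKM of 5 leaves fewer genes. For genes differing between 30 and 20 days in wild type (3645) the filter gave 2110 and the fold minimum 2196, and for genes differing between 30 and 20 days in mutant (3308) they gave 1903 and 1712. Without the 3 libraries richest in rRNA, which leaves 1 wild-type library at 20 days, assumed to vary like the rest, edgeR called 0 genes at 20 days (765 at an unadjusted p under 0.05; DESeq2 117, limma 66). With each library left out in turn the counts ranged over 11 to 414 at 20 days, 998 to 1433 at 30 days, 3376 to 3678 in wild type, 3009 to 3305 in the mutant and 1102 to 1513 for the interaction. Overlap in the same direction (3) became 17 with limma, 11 with DESeq2, 17 with library totals alone and 0 with the fold minimum, and genes called in opposite directions at 20 and 30 days (93) became 1223, 268, 1225 and 40; with each library left out they ranged over 0 to 8 and 9 to 278, both highest without 20-day mutant replicate 3. Lists called (3 at 20 days, 3 at 30 days, 4 in wild type and 3 in the mutant over time, and 3 for the interaction) fell to 0 in each comparison with an estimated correlation (1, 1, 0, 1 and 1 at an unadjusted p under 0.05); they were 5 in the mutant over time without a filter and with camera on log2(FPKM + 1), and 5 at 20 days without 20-day mutant replicate 3. Cytosolic ribosomal proteins in the mutant over time reversed under quantile normalization (adjusted p = 0.696), and cell division at 30 days lost its call with camera on log2(FPKM + 1) (adjusted p = 0.733). Of 531 values of named genes under 9 other settings 511 kept direction and call, 18 lost the call and 2 reversed: 13 lost it at 20 days under the replicate block, 2 at 20 days with quantile normalization, and 3 with equal FPKM totals. The reversals, both with equal FPKM totals, were the adenylyltransferase TraesCS1A02G419600 at 30 days (-0.29) and the proteinase inhibitor TraesCS1B02G322100 in wild type over time (0.00469), neither called there. Of 708 values with a library left out 611 kept both, 97 lost the call and 0 reversed. Low counts limit the genes near the filter and the non-coding RNA genes.

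Replicate numbers are shared between groups, but the libraries with one number did not deviate together (correlations of -0.08 to 0.01 within cultivar comparisons and in the mutant over time, and 0.21, -0.07 and 0.12 in wild type over time), and not every library correlated best with its own number, so the number was not taken as a pairing. With the replicate block the count at 20 days was 21, the overlap was 0 genes in the same direction and 17 in opposite directions, and no other count of genes moved by over 1.5 times.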

Other observations

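Both tests of the pattern on chromosome 1B were chosen after it was seen, as were the gene groups described here.

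Several other gene groups moved with time. Enzymes of starch and sucrose metabolism by KEGG pathway had 14 genes higher and 36 lower among 63 in wild type over time, with a median of -0.62 that turned to 0.44 with equal FPKM totals (camera adjusted p = 0.0203; adjusted p = 0.521 with an estimated correlation). In the mutant they had 16 higher and 27 lower and were not called (camera adjusted p = 0.513). Genes of terpenoid-quinone synthesis, the pathway that includes tocopherols, had 9 of 17 lower and 1 higher in wild type (median -0.46, turned to 0.60 with equal FPKM totals, camera adjusted p = 0.0212; adjusted p = 0.527 with an estimated correlation) and 9 lower and 0 higher in the mutant (median -0.57, camera adjusted p = 0.031; adjusted p = 0.445 with an estimated correlation). DNA replication genes had 21 of 32 lower and 4 higher in the mutant over time (median -1.32, camera adjusted p = 1.38e-05; adjusted p = 0.397 with an estimated correlation). In wild type they had 18 lower and 9 higher and were not called (camera adjusted p = 0.255), with a median of -0.57 that turned to 0.48 with equal FPKM totals. Both 4-coumarate-CoA ligases fell in each cultivar over time (medians -2.87 in wild type and -1.92 in the mutant), and both hydroxycinnamoyltransferases, which act next to them in phenylpropanoid synthesis, rose (2.34 and 1.94). In the mutant 1 of the ligases was called with quantile normalization and 1 of the transferases with equal FPKM totals.

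Few genes were expressed in the first 225 Mb of chromosome 1B, and no group of the design bears on it, so no explanation by cultivar or time was tested. Poor gene models there are argued against, since among genes with a KEGG annotation 16.9% were expressed, against 41.8% on 1A and 42.8% on 1D. The share was low in 12 of 12 libraries (9.12% to 13.0%, against 31.9% to 39.4% on 1A and 35.1% to 42.2% on 1D), whereas the rest of 1B had 39.8%. A chromosome arm that differs from the reference in both cultivars, such as a rye arm carried by some wheat cultivars, may account for this; it stays a hypothesis, since no sequence was examined.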
